A study of Mus musculus with 4 samples.

How the data were processed

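Brain endothelial cells of C57BL/6 mouse embryos at embryonic day 18 were profiled by RNA sequencing, per the labels, in 2 libraries of the genotype STING ECKO (replicates 1 and 2) and 2 libraries of wild type (WT, replicates 3 and 5). The series' design text speaks of triplicates; the 2 libraries per genotype in the labels were analysed here. The labels do not say that libraries of one genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical for WT. The STING ECKO libraries were not repeats of one sample, as the Y-linked gene Ddx3y had 3623 reads in STING ECKO 1 and was not listed for STING ECKO 2.

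The values came as 2 tables, one setting STING ECKO 1 beside WT 3 and the other STING ECKO 2 beside WT 5. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the genome build mm9; strand settings and the annotation release are not given in the sources used here. The deposited count columns hold whole reads per gene, per the file headers. The deposited normalized columns are CPM, the reads of a gene scaled to a common library total, with a 0 written by the authors as 0.5 read. The authors' fold change column is the ratio of the CPM values, and their log2 column is the log2 of that ratio. The authors' p-value columns compare 1 library with 1 library, so they concern those libraries and not the genotypes. Positions in the tables were compared with the GENCODE gene annotation of GRCm38: 16041 of 17872 matched genes (89.8%) had identical positions, and 99.8% had an end within 1000 bases. Coordinates are printed as the tables give them, and they are those of GRCm38 although the notes name mm9.

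The tables hold 16378 and 15627 genes. A table lists a gene only where both libraries had at least 1 read, or where one had 0 and the other at least 5, so an unlisted gene had at most 4 reads in either library. The 14100 genes in both tables were analysed, and the 3805 genes listed in one table entered as an alternative with missing values set to 0. Spreadsheet-altered symbols of 20 genes in the second table were restored from the first table or from the gene identifier. All columns of single libraries were assigned to a sample.

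Reads listed per library were 18610298 in STING ECKO 1, 22169261 in STING ECKO 2, 21472677 in WT 3 and 20591981 in WT 5, so that 1 read was 0.0537, 0.0451, 0.0466 and 0.0486 CPM. Counting intervals (95%, exact binomial) and the floor of 3 reads per library used against groups without reads cover counting error only, since reads were not tied to single molecules. Every fold given as at least a value is a bound on counting error alone, and zeros far exceeded that error. Of genes at 5 to 20 CPM in the mean of the other libraries, 15.7% had 0 reads in STING ECKO 2. Poisson counting gives 3.6e-49% there. At 1 to 5 CPM the share at 0 reads was 8.88% in STING ECKO 1, 36.2% in STING ECKO 2, 15.3% in WT 3 and 6.41% in WT 5.

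Genotypes were compared with edgeR 4.0.16 (R 4.3.3): filterByExpr with a minimum count of 10, TMM factors, and the quasi-likelihood test with Benjamini-Hochberg adjustment over 13365 genes at a threshold of 0.05. CPM values in the text use the TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01 and adjustment over 35 lists, beside an estimated correlation and fry; fry tests whether the genes of a list move one way on balance. DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom, other scalings and filters, a block by deposited table, and leaving out each library were alternatives. Leaving out a library leaves its genotype without a replicate, so the spread in those fits comes from the other genotype alone. The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Taking in the genes of one table, minimum mean levels for the gene and list tests, limma-trend on log2 CPM with a pseudocount, a minimum list size, and an estimated correlation without each library were added after seeing the data. A planned fit on RPKM was not run because the files give CPM.

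The rule named Tmem173 (Sting1), then genes past the adjusted threshold. As no gene passed, it named the 5 genes per direction with the smallest unadjusted p whose genotypes did not overlap and whose mean was at least 5 CPM, and up to 4 members with the smallest p from each list described. No predicted gene had to be skipped. The 14 lists described singly were chosen from the 35 after their values were seen.

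The test was tried on simulated counts with the means and library sizes of the 13365 genes, in 5 runs. The spread was the trend at each level, the same in every library, without differences in spread from gene to gene. The simulation also left out the excess of zeros in STING ECKO 2, so its rates may not be those of these data. The test called 3.80% of genes changed 2-fold, 16.0% at 4-fold, 40.4% at 8-fold and 62.8% at 32-fold, with 12 false calls over the 5 runs. Among genes with a mean of at least 50 CPM it called 11.8%, 45.5%, 81.4% and 97.5%. A simulated list of 20 genes shifted by 1 log2 unit was called in 3 of 5 runs with the preset correlation and in 0 of 5 with the estimated one, and 0 of 170 unshifted lists were called. Simulated genes were drawn independently of each other, so these runs cannot tell whether the preset correlation was too small for the real lists. As the estimated correlation called no shifted list, a high adjusted p with it does not decide either way. Transcript GC content and length came from the GENCODE transcripts, with a lowess span of 0.3. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used for tables and plots.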

Results

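RNA of mouse brain endothelial cells at embryonic day 18 was sequenced and counted per gene. STING, encoded by Tmem173 (Sting1), is an adaptor of cytosolic DNA sensing, and the genotype label STING ECKO names an endothelial knockout of it. There were 2 STING ECKO and 2 WT libraries, with 18610298 and 22169261 reads in STING ECKO 1 and 2 and 21472677 and 20591981 in WT 3 and 5. The comparison asked which genes differ in endothelial cells between the genotypes.

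Tmem173 (ENSMUSG00000024349, chromosome 18, 35733678 to 35740554, minus strand, GRCm38) was at 3.65 CPM in STING ECKO 1, 8.32 in STING ECKO 2, 4.48 in WT 3 and 6.27 in WT 5, from 67, 182, 97 and 130 reads. Its level was 5.99 ± 3.30 CPM in the libraries labelled STING ECKO and 5.38 ± 1.26 in WT (SD, n = 2 each; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, log2 fold change 0.16, SE 1.26, adjusted p = 1.00). The library labelled STING ECKO 2 had the highest level of the 4, so the gene did not separate the labels, and directions below rest on the labels. A count over the whole gene includes exons outside a deleted part, which the sources used here do not give. The sign turned without STING ECKO 2 (-0.55) and without WT 3 (-0.06).

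Endothelial genes were abundant in all 4 libraries. The 30 members of the endothelial list had median levels of 547, 473, 558 and 571 CPM in STING ECKO 1, STING ECKO 2, WT 3 and WT 5. Cldn5, a tight junction protein of brain endothelium named after its values were seen, was at 10487, 12536, 10853 and 10529 CPM. Medians of neural lists were lower: that of the neuron structure list was 4.85, 1.46, 8.58 and 6.34 CPM, and that of the oligodendrocyte precursor list 0.818, 0.183, 1.62 and 0.241 CPM. Pericyte RNA was present: the pericyte and smooth muscle list had medians of 171, 185, 182 and 148 CPM. Its member Rgs5, at 6849, 7225, 5591 and 4876 CPM, lay above the endothelial list medians. So did Apoe of the astrocyte list, at 717, 638, 743 and 1193 CPM.

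**Figure D1:**
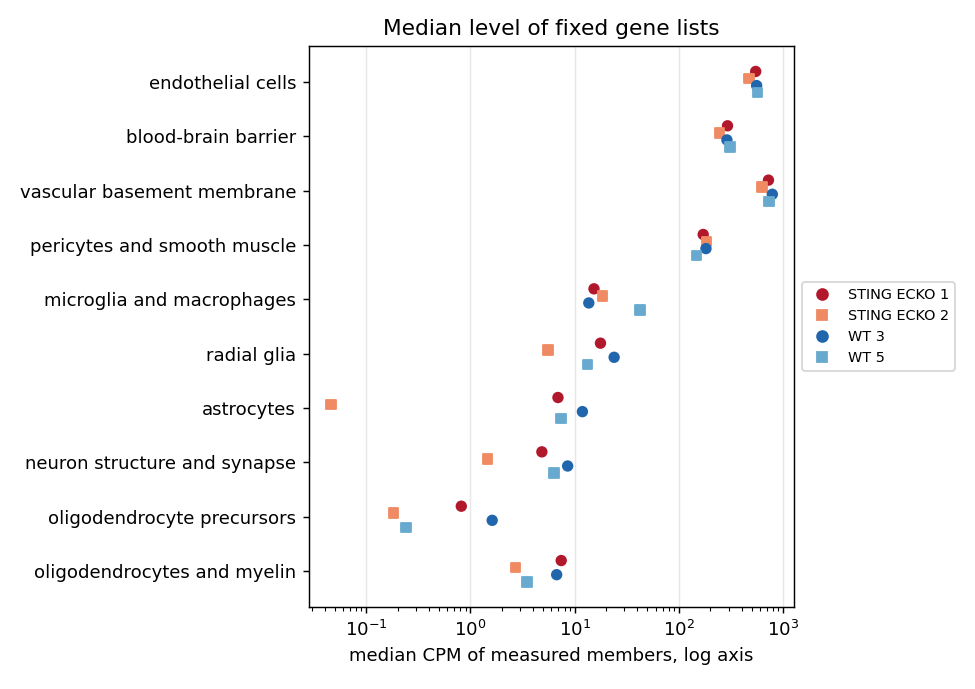
Median CPM of the measured members of 10 gene lists (log axis), with 1 symbol per library and no error bars. Endothelial medians lie between 473 and 571 CPM in all 4 libraries, and the astrocyte median of STING ECKO 2 lies at 0.0457 CPM.

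No gene passed the genotype test. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 13365 genes (smallest adjusted p = 0.977), with 642 genes (4.80%) at an unadjusted p under 0.05. DESeq2 called 93 genes, 48 higher and 45 lower in STING ECKO, and the edgeR likelihood ratio test called 33, all among the 93; limma-voom called 0. On the mixed grouping of STING ECKO 1 and WT 5 against the rest DESeq2 called 146 genes, and on STING ECKO 1 and WT 3 against the rest 12. Of the 93, 35 had at most 5 reads in each STING ECKO library, 26 had at most 5 in each WT library, and 16 had a mean of at least 50 CPM. The genotypes did not overlap in 4594 genes (34.4%), where chance gives 33.3%.

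The genes named by the rule are given as values that did not pass. They had the smallest p per direction among genes of at least 5 CPM whose genotypes did not overlap. Hes1, a transcriptional repressor downstream of Notch (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), was at 300 ± 51.9 CPM in STING ECKO and 88.6 ± 10.5 in WT (SD, n = 2 each), a log2 fold change of 1.76 (SE 0.26). Rnf187, a ubiquitin ligase (ENSMUSG00000020496, chromosome 11, 58932288 to 58938916), was at 399 ± 66.1 and 120 ± 2.19 CPM, a log2 fold change of 1.73 (SE 0.23). Surf6, a nucleolar protein (ENSMUSG00000036160, chromosome 2, 26888628 to 26902879), was at 132 ± 14.3 and 25.5 ± 2.41 CPM, a log2 fold change of 2.37 (SE 0.34). H1f0, a linker histone (ENSMUSG00000096210, chromosome 15, 79028212 to 79030498), was at 1189 ± 202 and 436 ± 64.1 CPM, a log2 fold change of 1.45 (SE 0.22). Cd276, an immune checkpoint ligand (ENSMUSG00000035914, chromosome 9, 58524298 to 58555437), had 395 and 751 reads in STING ECKO and 0 and 1 in WT, a ratio of 1158 with a counting interval of 216 to 47723.

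Among the lower genes, Atad1, a mitochondrial ATPase (ENSMUSG00000013662, chromosome 19, 32672563 to 32712298), was at 55.9 ± 13.3 CPM in STING ECKO and 161 ± 1.59 in WT (SD, n = 2 each), a log2 fold change of -1.53 (SE 0.31). Per2, a circadian clock repressor (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324), had 3 and 1 reads in STING ECKO and 793 and 367 in WT, a ratio of WT over STING ECKO of 260 with a counting interval of 107 to 1012. Nfkbid, a regulator of NF-kB (ENSMUSG00000036931, chromosome 7, 30421732 to 30428746), had 2 and 1 reads against 339 and 331, a ratio of 204 with an interval of 72.2 to 1031. Sema4a, a semaphorin (ENSMUSG00000028064, chromosome 3, 88435959 to 88461182), had 0 reads in both STING ECKO libraries and 353 and 745 in WT, at least 174-fold lower over a floor of 3 reads per library. Apba2, an adaptor that binds amyloid precursor protein (ENSMUSG00000030519, chromosome 7, 64501706 to 64753878), had 0 reads in both and 566 and 189 in WT, at least 117-fold lower. Both bounds cover counting error alone. Of genes at 5 to 20 CPM in the mean of the other libraries, 1.40% had 0 reads in STING ECKO 1 and 15.7% in STING ECKO 2. All 10 genes had an adjusted p of 0.977 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and all 10 passed in DESeq2, with adjusted p from 6.16e-07 (Rnf187 and H1f0) to 0.0122 (Atad1).

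**Figure D2:**
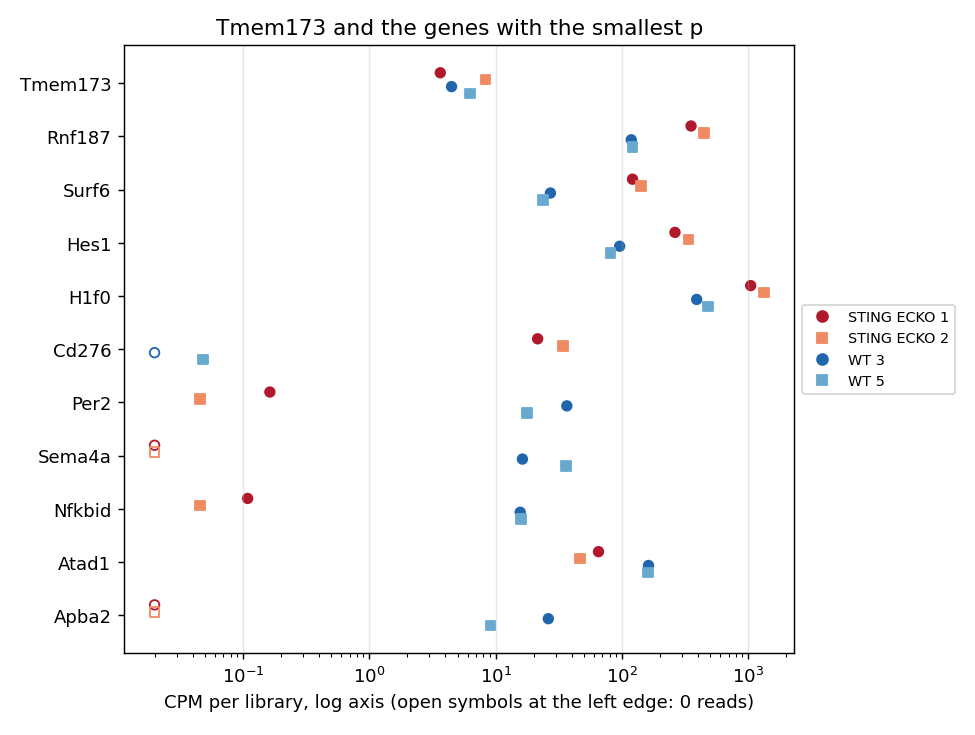
CPM of Tmem173 and of the 10 genes with the smallest p in each library (log axis), 1 symbol per library, with open symbols for 0 reads. Hes1 lies at 263 and 337 CPM in the STING ECKO libraries and at 96.0 and 81.2 in WT, while Tmem173 overlaps.

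Astrocyte genes were the only list of 35 past the camera test. All 10 tested members had a log2 fold change below 0, with a median of -0.52 and a mean log2 CPM difference of -2.29. Setting Acsbg1, an extreme member, to its bound cannot move that median. Of the members, 0 passed over all genes and 0 adjusted over the list alone. The list fell in STING ECKO with an adjusted p of 0.00868 by camera in limma (preset correlation), and its adjusted p = 0.941 with an estimated correlation. The mixed grouping of STING ECKO 1 and WT 3 against the rest also gave 1 list past camera. Acsbg1, an acyl-CoA synthetase, had 0 reads in both STING ECKO libraries and 113 and 153 in WT, at least 41.9-fold lower. Aqp4, the water channel of astrocyte endfeet, had 12 and 0 reads against 257 and 141, and Fgfr3, a growth factor receptor, 8 and 1 against 158 and 53. Apoe, a lipid carrier that other cells also express, was at 717 and 638 CPM against 743 and 1193. Without STING ECKO 2, the library with the most genes at 0 reads (13.2% of 14100, against 2.39% to 5.25% in the others), the adjusted p was 0.171 and the median -0.27; the median was -4.06 without STING ECKO 1, -0.98 without WT 3 and -0.30 without WT 5.

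**Figure D3:**
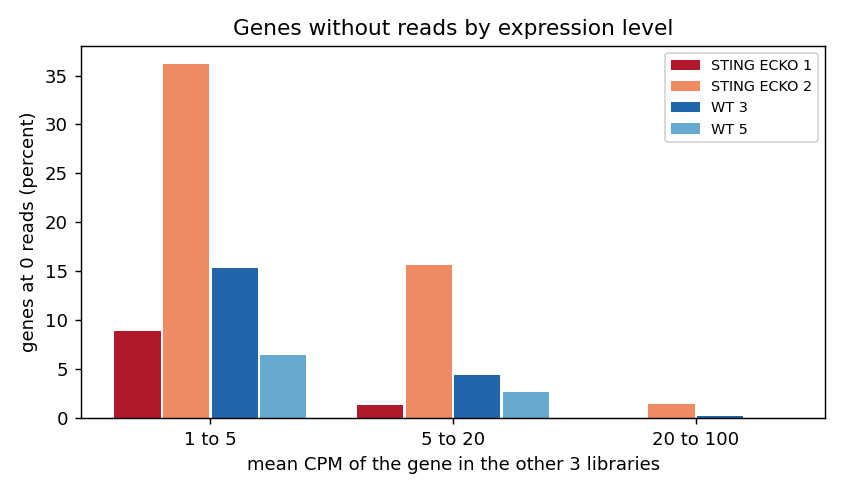
Percent of genes at 0 reads in each library (bars), by the mean CPM of the gene in the other 3 libraries (x axis). At 5 to 20 CPM the bar of STING ECKO 2 stands at 15.7% and the highest of the others, WT 3, at 4.46%.

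Neuron structure genes were below 0 in 13 of 17 tested members (adjusted p = 0.184 by camera in limma), 0 past the test over all genes and 0 adjusted over the list alone. Syn1, a synaptic vesicle protein, had 0 reads in both STING ECKO libraries and 279 and 291 in WT, at least 89.6-fold lower. Gap43, a growth cone protein, had 1 and 0 reads against 228 and 399, a ratio of 546 with a counting interval of 106 to 23547. The median log2 fold change of the list was -0.60. It was 0.05 without STING ECKO 2, 0.05 without WT 3, -1.78 without STING ECKO 1 and -1.14 without WT 5, while the camera direction stayed lower in each.

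Microglia and macrophage genes were below 0 in 18 of 22 members, with 0 past the test over all genes and 0 adjusted over the list alone (adjusted p = 0.125 by camera in limma). WT 5 stood apart: Mrc1, a macrophage mannose receptor, was at 258 CPM there and at 24.3, 21.0 and 21.7 in STING ECKO 1, STING ECKO 2 and WT 3, and Pf4 at 103 against 13.3, 16.2 and 22.5. C1qb, a complement component, was at 84.8 and 73.0 CPM in STING ECKO and 117 and 247 in WT. The median log2 fold change of the list was -0.89 with all libraries, -1.40 without WT 3 and -0.23 without WT 5. With all libraries and an estimated correlation its adjusted p was 0.941 by camera in limma.

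Pericyte and smooth muscle genes were above 0 in 10 of 13 members, with 0 past the test over all genes and 0 adjusted over the list alone (adjusted p = 0.125 by camera in limma). Their median log2 fold change was 0.25, while their mean log2 CPM difference was -0.27. Rgs5 had a log2 fold change of 0.43 (SE 0.15) and Kcnj8, a potassium channel, 0.37 (SE 0.17). Acta2, smooth muscle actin, had 0 reads in both STING ECKO libraries and 31 and 55 in WT, at least 13.6-fold lower. That bound covers counting error alone. At 1 to 5 CPM in the mean of the other libraries, 8.88% of genes had 0 reads in STING ECKO 1 and 36.2% in STING ECKO 2.

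Of 30 endothelial genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.785 by camera in limma). Robo4, an endothelial guidance receptor, was at 579 and 554 CPM in STING ECKO and 914 and 820 in WT, and Vwf, a haemostatic glycoprotein, at 949 and 827 against 1204 and 1182. For the blood-brain barrier list, 0 of 18 genes passed over all genes and 0 adjusted over the list alone (adjusted p = 0.785 by camera in limma). Its member Cav1, a caveolar coat protein, was at 287 and 151 CPM against 376 and 462, and Mfsd2a, a lipid transporter, at 1759 and 1452 against 2013 and 2013. Of 15 basement membrane genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.838 by camera in limma). Hspg2, the proteoglycan perlecan, was at 291 and 414 CPM against 233 and 158. Their median log2 fold change was -0.06 and their mean log2 CPM difference 0.13.

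Genes of secreted endothelial factors were below 0 in 10 of 16 members, with 0 past the test over all genes and 0 adjusted over the list alone (adjusted p = 0.731 by camera in limma). Cxcl12, a chemokine, was at 420 and 448 CPM in STING ECKO and 578 and 503 in WT, and Pdgfb, a growth factor for pericytes, at 158 and 239 against 165 and 162. The oligodendrocyte precursor list had 7 tested genes and the myelin list 8, with 0 past the test over all genes and 0 adjusted over the list alone in each (adjusted p = 0.879 and 0.825 by camera in limma). Cspg4, which pericytes also express, was at 83.8 and 152 CPM against 155 and 181. Sox8, a transcription factor, had 54 and 15 reads in STING ECKO and 0 in both WT libraries, at least 12.8-fold higher. That bound covers counting error alone. At 1 to 5 CPM in the mean of the other libraries, 15.3% of genes had 0 reads in WT 3 and 6.41% in WT 5.

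Genes of the STING pathway were below 0 in 7 of 11 members and interferon response genes above 0 in 19 of 24, with 0 past the test over all genes and 0 adjusted over the list alone in each (adjusted p = 0.785 and 0.418 by camera in limma). Ifitm3, an antiviral membrane protein, was at 135 and 153 CPM in STING ECKO and 97.4 and 110 in WT, and Rtp4 at 193 and 116 against 100 and 107. The interferon list had a median log2 fold change of 0.43 and a mean log2 CPM difference of -0.17. Its median was 0.72 without STING ECKO 2 and -0.31 without STING ECKO 1, where the camera direction turned too. By level, STING ECKO 1 alone stood high. The median of the measured members was 28.5 CPM there and 14.7, 12.7 and 19.9 in STING ECKO 2, WT 3 and WT 5. Of 11 Notch genes, 0 passed over all genes and 1 adjusted over the list alone, which was Hes1 (adjusted p over the list 0.0101 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The list itself had an adjusted p of 0.981 and the Wnt target list, with 0 of 10 genes past the test over all genes and 0 adjusted over the list alone, of 0.836, both by camera in limma.

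Differences between libraries of one genotype were of the size of those between genotypes, with no test made. STING ECKO 1 and 2 had a median absolute log2 CPM difference of 0.85 and WT 3 and 5 of 0.58, and the 4 pairs across genotypes ranged from 0.55 to 0.91. Means were 0.72 within and 0.73 between genotypes. The differences of the deposited pairs, STING ECKO 1 minus WT 3 and STING ECKO 2 minus WT 5, correlated across genes at r = -0.0199, with 50.1% of genes of the same sign. Crossed pairs gave r = 0.177 and 50.8%, and the differences within genotypes, STING ECKO 1 minus 2 and WT 3 minus 5, gave r = -0.187 and 47.8%; genes are not independent replicates. At a mean of at least 50 CPM the deposited pairs gave r = 0.0541 and the crossed pairs 0.0345.

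The authors' deposited tables marked 6702 of 16378 genes between STING ECKO 1 and WT 3, 3526 higher and 3176 lower in STING ECKO. The authors' deposited table of STING ECKO 2 and WT 5 marked 8142 of 15627 genes, 2655 higher and 5487 lower. Among the 14100 genes in both, the authors' deposited tables marked 3425 in both, 1707 in the same direction and 1718 in opposite directions, where independent marks would give 1141 and 1181. In the authors' deposited tables every marked gene had an absolute log2 fold change of at least 1 and an unadjusted p of at most 0.0497. The adjusted p in the authors' deposited tables lay below the unadjusted p for 86.4% and 89.2% of genes, which a Benjamini-Hochberg adjustment of those p-values cannot give. These tests compare 1 library with 1 library.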

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

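The test of sequencing depth, the test of all cells other than endothelial cells and the comparison of splits were chosen after the result was seen, as was the minimum of 500 reads used here.

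Genes that only one table lists entered the genotype test in an alternative alone (0 of 13725 genes called by the edgeR quasi-likelihood test), and 8 of them had at least 500 reads in a STING ECKO library and 0 in the WT library of that table. In STING ECKO 1 these were the Y-linked genes Ddx3y (3623 reads), Eif2s3y (939) and Uty (526). In STING ECKO 2 they were Nhlrc1 (839 reads), Gm5127 (641), Pfn4 (639), Homer2 (604) and H2-Ab1 (598). Xist had 0 reads in STING ECKO 1 and 876, 2347 and 3374 in STING ECKO 2, WT 3 and WT 5. By the Y-linked genes and Xist, STING ECKO 1 was male and the other libraries were female. Sex thus enters both the genotype comparison and the spread between the STING ECKO libraries. Its effect on other genes was not tested.

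STING ECKO 2 had 1855 of 14100 genes at 0 reads, against 378, 740 and 337 in STING ECKO 1, WT 3 and WT 5. Lower depth is argued against, since it had 1.08 times the reads of WT 5, the library with the fewest zeros. Among genes at 5 to 20 CPM in the mean of the other libraries, 15.7% had 0 reads in STING ECKO 2 and at most 4.46% in any other. This met the bound set in advance for fewer transcripts captured from that sample. It restates the excess of zeros at that level, so it cannot tell that cause from others. The rest of that test was met only in part. In STING ECKO 2, 2 of 22 cholesterol genes and 2 of 26 cell cycle genes had 0 reads, but 0 of 22 respiratory and 0 of 30 ribosomal genes. Neural genes were at 0 more often than matched genes (29.7% of 91 members, against a median of 18.7% and an upper bound, set in advance, of 26.4% in 10000 random lists), so less neural RNA in that sample may add to it. Both stay open, as does a biological difference between embryos, which was not tested.

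The 10 named genes were selected for genotypes that do not overlap, so that property is no finding. GC content or length bias cannot be told apart from other causes. A correction left the median absolute log2 fold of the 10 genes at 1.01 times its value. However, 5 of them had at most 3 reads in each library of a genotype, which no such correction could offset. Of the rest, Atad1 went from -1.55 to -1.16 and Rnf187 fell slightly. Surf6 went from 2.36 to 2.55, Hes1 from 1.75 to 1.86 and H1f0 from 1.44 to 1.57. The 4 libraries allow 3 splits, too few for a share under 0.05: 2 of the 3 gave at least as many genes at an unadjusted p under 0.05, with 642 in the real split and 739 in the highest other, STING ECKO 1 and WT 5 against the rest. At a mean of at least 50 CPM the real split gave 200 genes and the others 127 and 131, with 0 called in each, and DESeq2 called 93 in the real split and 146 and 12 in the others. An effect of genotype on these genes was neither shown nor excluded.

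The astrocyte list was lower in STING ECKO with the preset correlation (adjusted p = 0.00868 by camera in limma). It was not past the threshold with an estimated correlation (adjusted p = 0.941 by camera) or with fry (adjusted p = 0.405 in limma). With an estimated correlation 0.941 was the smallest adjusted p of all 35 lists, and 0 of 5 simulated shifted lists were called. That setting therefore does not decide. A lower share of all cells other than endothelial cells cannot be told apart: 11 pericyte and smooth muscle genes at 20 CPM or more had a mean log2 difference of 0.31 (SE 0.08 over genes), but all 13 tested members had -0.27 (SE 0.41), and the minimum level leaves out genes that were low in STING ECKO. Few captured transcripts in STING ECKO 2 cannot be told apart from a difference of both libraries, since without it the median was -0.27, between the bounds set for either case. Less astrocyte RNA carried into the STING ECKO samples and an effect of genotype both stay open and were not tested.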

How the results depend on the processing

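The minimum mean levels of 10 and 50 CPM for the gene and list tests, the genes of one table, limma-trend, the minimum list size and the estimated correlation without each library were chosen after seeing the data. In 16 alternatives, limma-voom and limma-trend among them, 0 genes were called, while DESeq2 called 93 and the likelihood ratio test 33; the cause was not tested. The number of genes at an unadjusted p under 0.05 in the edgeR quasi-likelihood test was 642 with all libraries, 2668 without STING ECKO 1, 595 without STING ECKO 2, 162 without WT 3 and 243 without WT 5. The genotypes share no replicate number in the labels; a block by deposited table gave 0 calls and 273 genes at an unadjusted p under 0.05 in the same test. At a mean of at least 50 CPM, 200 of 4061 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.113 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). By depth alone, 0 reads allow up to 0.161 CPM in STING ECKO 1, 0.135 in STING ECKO 2, 0.140 in WT 3 and 0.146 in WT 5. The number of lists past camera was 0 with an estimated correlation, 0 with fry and 0 at a mean of at least 10 CPM. Which lists passed changed with the library left out. Without STING ECKO 2 the interferon response list passed in place of the astrocyte list. Without WT 3 the microglia and macrophage list passed beside the astrocyte list. These fits leave a genotype without a replicate, and the lists did not pass in them with an estimated correlation. The adjusted p of the astrocyte list was 0.941 with an estimated correlation, 0.405 with fry, 0.303 at a mean of at least 10 CPM (limma), 0.00846 to 0.171 without each library, and, with an estimated correlation, 0.998 without STING ECKO 1, 0.992 without STING ECKO 2, 0.996 without WT 3 and 0.920 without WT 5. It kept its direction in all 16 alternatives. The log2 fold change of Tmem173 ran from -0.55 to 0.63 without each library. Leaving out each library gave -0.045 to 0.55 for Pdgfb, -0.90 to 0.11 for Edn1, -3.51 to 0.069 for Mrc1, -0.72 to 0.26 for Jag1, -0.59 to 2.46 for Sox6, -1.02 to 8.15 for Nkx6-2, -8.48 to 0.84 for Ikbke and -0.75 to 0.0089 for Col4a1; fewer samples entered these fits. The mean of the median absolute log2 differences was 0.53 between genotypes and 0.53 within them at a mean of at least 10 CPM, with fewer genes. The 10 named genes were run in 8 alternatives, where their direction says nothing of stability, since they were selected for genotypes that do not overlap; all 10 passed in DESeq2.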

Other observations

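The other 21 lists did not pass camera (adjusted p from 0.241 to 0.981 in limma). Adjusted over the list alone, 1 gene was higher in STING ECKO in them, Hes1 as a member of the radial glia list. The serotonin transporter Slc6a4 was lower (0 reads in both STING ECKO libraries, at least 30.8-fold lower by counting error alone). At 1 to 5 CPM in the mean of the other libraries, 8.88% of genes had 0 reads in STING ECKO 1 and 36.2% in STING ECKO 2. Slc6a4 was the 1 tested gene of the midbrain and hindbrain list, so its p of 0.0216 (edgeR quasi-likelihood test) is in effect unadjusted. Over all genes, 0 passed. Immediate early genes, which respond to cell stimulation, were below 0 in 10 of 11 members (adjusted p = 0.515 by camera in limma), and oxidative phosphorylation genes above 0 in 15 of 22 (adjusted p = 0.515 by camera in limma), with a median log2 fold change of 0.24 that was -0.03 without STING ECKO 2. The haemoglobin gene Hba-a1, named after its values were seen, varied within genotypes, at 943 and 2450 CPM in STING ECKO 1 and 2 and 2003 and 1024 in WT 3 and 5. Tspo2, also of the erythroid list, had 146 and 264 reads in STING ECKO and 0 and 2 in WT. Of the 7 tested members of that list, 4 were above 0 and 3 below.

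The first principal component held 58.1% of the variance of log2 CPM and set STING ECKO 2 apart. Genes with at least 100 reads in 2 libraries and at most 4 in the others numbered 12 for the STING ECKO pair and 50 for the WT pair. They numbered 60 for STING ECKO 1 with WT 5 and 44 for STING ECKO 1 with WT 3. For STING ECKO 2 they numbered 6 with WT 5 and 18 with WT 3. The pairs with STING ECKO 2 thus had the lowest numbers, whichever the genotype of the other library.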
